A study of Homo sapiens with 2 samples.

How the data were processed

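Total RNA from FaDu cells, an established line from a human hypopharyngeal squamous cell carcinoma, was sequenced in 2 libraries at day 2. Per the labels, 1 library came from cells with a control shRNA and 1 from cells with an shRNA against KIF2C, and an MGI platform was used for library preparation and sequencing. A short hairpin RNA (shRNA) is a small expressed RNA that is processed to degrade a matching mRNA.

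The deposited table names its libraries by the codes C1 and D1, and no label spells out which code is the control. The letters were read as control and knock-down, and the expression of KIF2C goes against that reading. The reading was not exchanged on the strength of an expression value. The libraries are therefore named by their codes throughout, every difference is library D1 against library C1, and which of them is the knockdown is not established.

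The estimated counts per gene were made by the authors and are unnormalized, per the file headers; 48.9% of the values in library C1 and 48.2% in library D1 were not whole numbers, as arises when reads are shared between genes or transcripts. Per the submitters' processing notes, Bowtie2 and RSEM were used with the hg38 build; versions and the gene annotation are not given in the sources used here. The TPM values were computed and deposited by the authors, per the file headers, and sum to 1000000 in each library. The FPKM values were likewise deposited by the authors, per the file headers. The deposited TPM and FPKM ratios were compared with the count ratios across the 10365 genes with at least 100 counts in both libraries. The Pearson r across genes was 0.993 for each. Once the median difference from the count ratios was subtracted, 94.9% of TPM and 95.0% of FPKM ratios lay within 0.1 on the log2 scale.

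The table holds 16951 genes with NCBI gene identifiers and symbols. Of these, 16887 (99.6%) matched a gene of the RefSeq annotation of GRCh38.p14, which gave the coordinates and the gene class, and 16823 were protein coding. The totals were 18189742 estimated counts in library C1 and 18560024 in library D1. Mitochondrially encoded mRNAs and nuclear-retained or small structural RNAs were not analysed here.

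The estimated counts were rounded to whole numbers. Effective library sizes were computed by the trimmed mean of M values (TMM) in edgeR 4.0.16 under R 4.3.3, with factors of 1.04 for library C1 and 0.960 for library D1. CPM values are counts per 1000000 of the effective library size, so that 1 CPM corresponds to 19.0 reads in library C1 and 17.8 in library D1. The log2 ratio of each gene was taken after adding 0.5 counts in each library, and the 95% interval is the exact Clopper-Pearson interval of the gene's share of reads in library D1, turned into a ratio. The intervals cover counting error only. Gene counts by size used a ratio of at least 2-fold among genes at 1 CPM or more in at least 1 library. The number that counting error alone gives was simulated in 100 draws of both libraries from their pooled profile. With 1 library per group no test between conditions was possible, no p-value is given, and no difference has a replicate check. A count of 0 allows up to 3 counts, and no fold is given against it.

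The 41 gene lists were fixed before the data were examined, for a squamous carcinoma line, a mitotic kinesin and the stated interest in proliferation and motility, with markers of 5 other kinds of cell. The median log2 ratio of a list with at least 5 members past the expression filter was placed among the medians of 10000 random lists of the same size, matched on mean log2 CPM in 20 bins. A list below percentile 2.5 or above percentile 97.5 is said to stand apart, which describes these 2 libraries only. Of the lists, 35 had a percentile, and 1.8 would stand apart by chance if their members varied like randomly drawn genes. Members of a list may vary together, and more lists would then stand apart between any 2 cultures. The named genes were KIF2C, the 10 highest and 10 lowest genes by the interval bound nearest to 0 among genes at 5 CPM or more in at least 1 library, and the 5 highest and 5 lowest by log2 ratio among genes at 100 CPM or more. Up to 4 members of each list with the largest absolute ratio were named as well; some members that this rule selects are not reported here. Rows with only clone, locus or small RNA symbols and pseudogenes were left out of the ranking. Any other gene named was chosen after its values were seen, and the text says so.

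The procedure was tested on simulated data for D1 against C1 with 16951 genes and known library sizes. All 50 genes changed 3-fold and all 50 changed 6-fold were found in each direction. The changed genes were drawn from those with at least 100 counts in at least 1 library. The interval held the simulated ratio for 94% of genes 3-fold higher, 92% of genes 6-fold higher, 98% of genes 3-fold lower, 90% of genes 6-fold lower and 95.3% of 12901 unchanged genes, of which 43 passed the 2-fold size rule. Of 100 random lists of 25 members, 4 stood apart, and 100 of 100 such lists shifted by 0.5 on the log2 scale stood apart above. Smaller lists, lists whose members vary together and changes in rarer genes were not tried.

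Alternatives fixed before the data were examined were size factors from DESeq2 1.42.0, library totals, upper-quartile scaling, 5 added counts, no expression filter, a filter of 10 CPM, other size rules, protein-coding genes only, random lists unmatched or matched in 50 bins, and the mean of a list. Alternatives chosen after seeing the data were the deposited TPM, genes whose estimated counts were whole in both libraries, and random lists matched also on transcript length or GC content. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the other steps.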

Results

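Gene expression was measured by RNA sequencing in FaDu cells, a line established from a squamous cell carcinoma of the hypopharynx, a cancer of the head and neck. The design compared cells carrying a control shRNA with cells carrying an shRNA against KIF2C, with 1 library of each at day 2, to ask how KIF2C bears on proliferation and motility. KIF2C is a kinesin-13 motor that removes tubulin from microtubule ends and helps correct faulty attachments of chromosomes to the spindle. Library C1 held 18189742 estimated counts and library D1 held 18560024, over 16951 genes. The most abundant mRNA was FTH1, the ferritin heavy chain, with 1.13% of the counts in library C1, and EEF1A1, a translation elongation factor, with 0.95% in library D1. No label ties the codes C1 and D1 to the conditions, so each difference below is library D1 against library C1 and not knockdown against control.

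KIF2C mRNA was 4.13-fold higher in the library labelled D1 than in the library labelled C1, with 3036 against 783 reads. Its log2 ratio was 2.04 (95% counting interval 1.93 to 2.16), and the deposited TPM values were 119.06 and 31.95. The gene (NCBI gene 11004) lies on chromosome 1 from 44739837 to 44767767 in GRCh38.p14. KIF2C ranked 3rd by higher ratio among 4170 genes of like abundance. The related kinesin-13 genes differed far less, KIF2A with a log2 ratio of -0.17 (2307 reads in library C1 and 1930 in library D1) and KIF24 with 0.26 (362 and 406 reads). The letters C and D would most simply be read as control and knock-down, and KIF2C goes against that reading, so which library is the knockdown is not established. No difference had a replicate check, and every interval covers counting error only.

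Keratins were 4 of the 10 genes ranked highest in library D1. KRT14 and KRT5, the keratin pair of basal squamous cells, had log2 ratios of 3.12 (3.01 to 3.23) and 2.77 (2.73 to 2.80). KRT5 had 6425 reads in library C1 and 41074 in library D1. KRT6A, a keratin of activated keratinocytes, had a ratio of 2.78, and KRT13, a keratin of mucosal squamous epithelium, 2.88. The other genes highest in library D1 were ACKR3, a scavenging chemokine receptor (2.78), PAK6, a p21-activated kinase (2.59), LY6D, a surface protein of squamous epithelium (2.49), DKK3, a secreted dickkopf family protein (2.31), and SNAI2, a transcription factor of the Snail family (2.05). Among abundant genes, PSAT1, an enzyme of serine synthesis, had a ratio of 1.98 and GPC1, a cell surface proteoglycan, 1.97.

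The lowest gene in library D1 among those ranked was DIO2, the deiodinase that activates thyroid hormone, with 1882 reads in library C1 and 57 in library D1, a log2 ratio of -4.94 (-5.36 to -4.57). AGR2, a protein disulfide isomerase of secretory epithelium, had 142 and 4 reads (-4.89), and C11orf86 had 96 and 3 (-4.69). SULT2B1, a cholesterol sulfotransferase, had a ratio of -4.12, SYTL2, a vesicle transport protein, -3.92, CP, the copper-carrying ferroxidase ceruloplasmin, -3.67, and HAS2, a hyaluronan synthase, -3.65. SPNS2, the sphingosine-1-phosphate exporter, had -3.30, TXNIP, the thioredoxin-binding protein that responds to glucose, -3.16, and ADAM12, a membrane metalloprotease, -3.03. Among abundant genes the lowest after TXNIP were GDF15, a stress-induced cytokine (-2.08), MX1, an interferon-induced antiviral GTPase (-2.05), LIF, a cytokine of the IL6 family (-1.99), and FN1, the matrix protein fibronectin (-1.99).

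**Figure D1:**
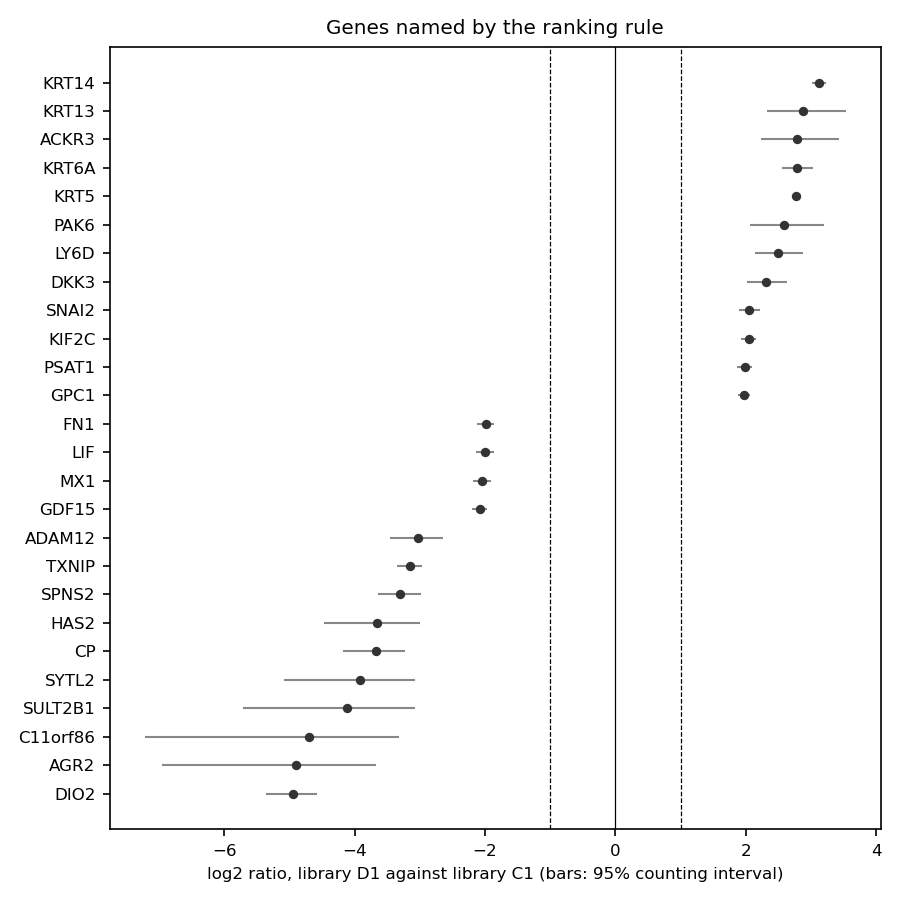
The log2 ratio of library D1 against library C1 (x axis) is plotted for the 26 genes chosen by rank, with 1 library each and bars for the 95% counting interval. KRT14 is the highest at 3.12, KIF2C lies at 2.04 and DIO2 is the lowest at -4.94; dashed lines mark 2-fold.

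Of 13225 genes past the expression filter, 318 were at least 2-fold higher in library D1 and 601 at least 2-fold lower, while 12306 (93.1%) lay between. Counting error alone gave a mean of 21.2 higher and 19.0 lower genes in 100 simulated pairs. At least 4-fold differences were found for 33 higher and 117 lower genes. Scaling by plain library totals shifted every ratio by -0.12 and moved the higher share of these genes from 34.6% to 23.8% (232 higher and 743 lower), and the deposited TPM gave 21.4% (213 and 783). With genes at 10 CPM or more the share was 44.2% (171 and 216), so the size of the excess of lower genes depended on scaling and on rare transcripts. Counts of list members above or below 0 in the following are those under TMM scaling. Across the 13225 genes past the filter, the log2 ratio rose with mean log2 CPM (Spearman rho 0.207). Members of a list of abundant genes may therefore lie above 0 without the list differing from other genes of like abundance. The counts above or below 0 take no account of this trend and are given without a background share, whereas the percentiles from matched random lists do account for it.

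**Figure D2:**
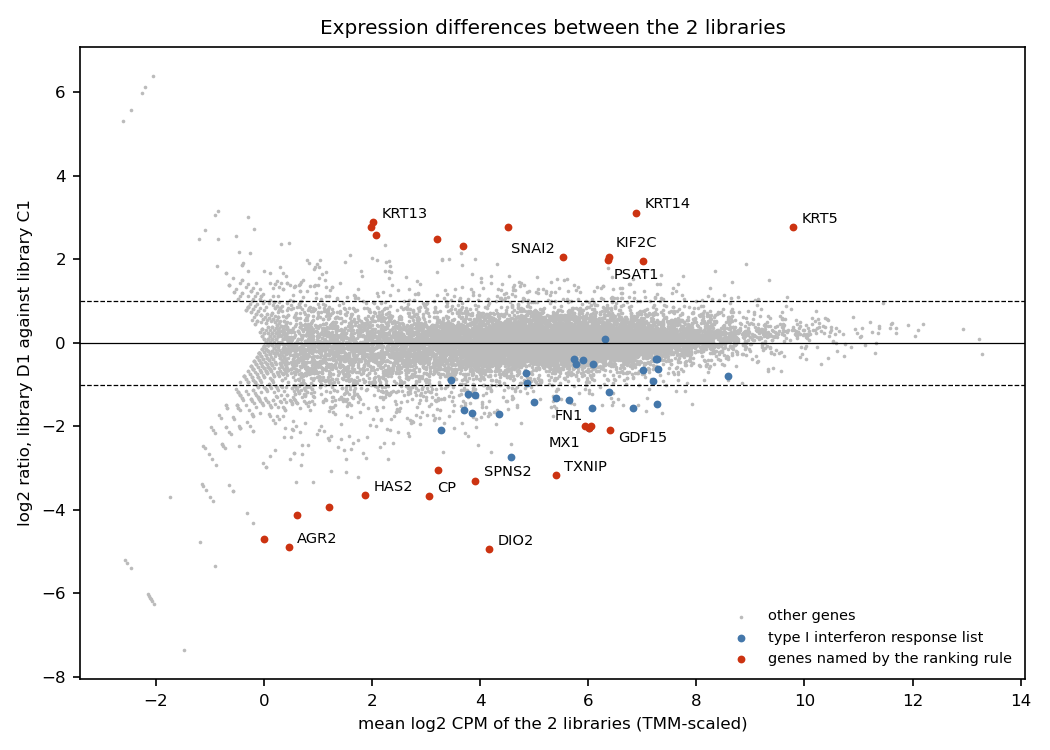
Each point is 1 gene, with its mean log2 CPM (x axis) and the log2 ratio of library D1 against library C1 (y axis), 0.5 counts being added so that genes at 0 in a library are shown; red marks the 26 genes chosen by rank, MX1 included, and dashed lines mark 2-fold. Of the 29 interferon response genes past the filter, 28 lie below 0 under the TMM scaling plotted.

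Genes of squamous identity were higher in library D1 as a group. Of 15 measured members, 8 were at least 2-fold higher, 1 was at least 2-fold lower and 6 lay between, and the list median of 1.06 lay at percentile 100 of matched random lists. Besides the keratins, NECTIN1, a cell adhesion receptor, had a ratio of 1.64. TP63, the master transcription factor of stratified epithelium, had 1869 and 4690 reads (1.42), while SOX2, a transcription factor of squamous progenitors, had 413 and 143 (-1.44); both were named after their values were seen. In the keratinocyte differentiation list, 3 of 11 members were at least 2-fold higher and 1 lower (median 0.47, percentile 99.84). They were KRT13, the mucosal keratin KRT4 (2.36) and TGM1, the transglutaminase that crosslinks the cell envelope (1.70), against S100A9, a calcium-binding alarmin (-1.60). Keratin genes resemble one another in sequence and part of their estimated counts were fractions, so the split of reads among them is uncertain. The differentiation list did not stand apart without the expression filter (19 members, percentile 96.5) or with whole counts only (7 members, 88.26).

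The Notch pathway list, which governs differentiation choices in stratified epithelium, was also higher in library D1. Of 13 members, 12 lay above 0, 4 were at least 2-fold higher and 1 lower (median 0.71, percentile 100). HES2, a repressor of the HES family, had a ratio of 1.93, the ligand DLL1 1.29 and the target HEYL 1.31, the last from 10 and 24 reads. HEY1, named after its value was seen, was the other higher member at 1.12, and the ligand DLL4 was lower with 28 and 3 reads (-2.94, interval -5.49 to -1.44). Epithelial adhesion genes went both ways, with 4 of 21 members at least 2-fold higher and 2 lower. The higher members were the desmosome genes DSG3 (1.51), PKP1 (1.32) and, named after their values were seen, DSC3 (1.09) and DSP (1.03). Other desmosome genes of the list, also named after their values were seen, differed less, with JUP at 0.24, PKP3 at 0.18, DSG2 at 0.12 and DSC2 at -0.21. The lower members were TJP3 (-2.40) and CLDN4 (-1.20). The list had a median of 0.02, a mean of -0.02 and percentile 16.31, and the sign of its median depended on the scaling.

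Type I interferon response genes were lower in library D1. Of 29 measured members, 15 were at least 2-fold lower, none was 2-fold higher and 28 lay below 0, with a median of -1.18 at percentile 0.0 of matched random lists. IFI44L, an interferon-induced gene, had 1168 and 164 reads (-2.74, interval -2.99 to -2.51). The antiviral GTPase MX2 had a ratio of -2.09, and XAF1, a pro-apoptotic interferon target, -1.71. Antigen presentation genes were lower by a smaller amount, with 15 of 17 members below 0 and 1 at least 2-fold lower (median -0.31, percentile 0.0). CD74, the invariant chain of class II molecules, had 37 and 10 reads (-1.75), NLRC5, the activator of class I genes, -0.77, HLA-F -0.73 and HLA-B -0.61. HLA genes share sequence, so reads split between them are uncertain.

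NF-kappaB targets and cytokines were lower on balance, with 6 of 21 members at least 2-fold lower, 3 higher and a median of -0.54 at percentile 0.0. After LIF, the inflammatory cytokine IL6 had a ratio of -1.75. The higher members were IL36G, an epithelial cytokine of the IL1 family (1.90), the growth factor CSF2 (1.44, from 15 and 39 reads) and IL1B (1.21), the last named after its value was seen. The 13 members with whole counts did not stand apart (percentile 13.82).

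Mitotic genes were slightly higher in library D1. None of 35 G2/M genes reached 2-fold, but 32 lay above 0 and the median of 0.23 stood at percentile 99.06. ANLN, a scaffold of the cleavage furrow, had a ratio of 0.81, CDC20, the activator of the anaphase-promoting complex, 0.66, the mitotic transcription factor FOXM1 0.56 and the checkpoint gene MAD2L1 0.56. Among the 24 members with whole counts the percentile was 95.05. The other mitotic kinesins did not stand apart (11 of 12 above 0, none at 2-fold, median 0.19, percentile 91.7), with KIF20A at 0.58, KIF4A at 0.50 and KIF18B at 0.48. G1/S and DNA replication genes had 26 of 34 members above 0 (median 0.17, percentile 96.0, or 97.6 by its mean and 98.21 with unmatched random lists), and the ribonucleotide reductase subunit RRM1 alone was at least 2-fold higher (1.21). The DNA replication clamp loader gene RFC3 had 0.65 and the phosphatase CDC25A -0.45. DNA repair genes gave no member at 2-fold (17 of 22 above 0, median 0.15, percentile 92.14), with BRCA1 at 0.48 and the helicase BLM at 0.39.

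Tubulin genes, most of which encode the alpha- and beta-tubulins of microtubules, were higher in library D1 on balance. Of 12 members, 10 lay above 0 and 2 below, none reached 2-fold upward, and the median of 0.54 lay at percentile 100. TUBB6 had a ratio of 0.79, TUBB4B 0.76 and TUBB2A 0.70, whereas TUBA1A had 814 and 271 reads (-1.49) and TUBD1, named after its value was seen, 808 and 631 (-0.27). Replication-dependent histone genes were lower, with 4 of 11 members at least 2-fold lower (median -0.88, percentile 0.44). These were H3C10 (-1.71, from 29 and 8 reads), H2AC6 (-1.31), H2BC4 (-1.15) and H3C4 (-1.09). Tubulin and histone genes have near-identical copies that share reads, and most replication-dependent histone mRNAs lack a poly(A) tail, so their yield depends on the library method. The histone list no longer stood apart without the expression filter (29 members, percentile 47.1) or by its mean (percentile 13.9), and the tubulin list lay at percentile 97.48 by its mean.

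Targets of p53 did not stand apart, with 2 of 23 members at least 2-fold higher and 1 lower (median -0.10, percentile 11.73). GADD45A, a stress-induced growth arrest gene, had a ratio of 1.12 and FDXR, a mitochondrial reductase, 1.04, against GDF15 at -2.08. Apoptosis genes had 2 of 21 members at least 2-fold lower and none higher (median -0.13, percentile 3.56). BMF, which encodes a pro-apoptotic BH3-only protein, had 112 and 10 reads (-3.33), and BIRC3, an inhibitor of apoptosis induced by NF-kappaB, had -1.54. By its mean the apoptosis list stood apart below (percentile 0.72).

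Among the genes tied to motility, matrix proteases and mesenchymal genes were lower in library D1 and cytoskeletal genes were higher. Of 20 extracellular proteases and inhibitors, 4 were at least 2-fold lower and 1 higher (median -0.35, percentile 0.05). The matrix metalloprotease genes MMP9 (-1.51), MMP1 (-1.48), MMP10 (-1.34) and MMP3 (-1.25) were the lower members, with 4907 reads of MMP1 in library C1 and 1658 in library D1. The higher member was ADAMTS1 (1.06, from 42 and 83 reads), named after its value was seen. Mesenchymal genes had 3 of 15 members at least 2-fold lower and 2 higher (median -0.42, percentile 1.69). FN1 (-1.99), the matrix glycoprotein TNC (-1.66) and the collagen gene COL1A1 (-1.18) were lower, while SNAI2 (2.05) and the actin-binding TAGLN (1.13), the latter named after its value was seen, were higher. The mesenchymal list did not stand apart without the expression filter (percentile 7.85), with 5 counts added (4.31) or by its mean (9.85).

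Integrin and focal adhesion genes had 17 of 25 members above 0 (median 0.29, percentile 99.5). ITGB4, the hemidesmosome integrin, was the member at least 2-fold higher (1.03), the laminin chain gene LAMA3 had 0.72, and the integrin gene ITGB8 had -0.92. Actin and motility genes had 21 of 26 members above 0 (median 0.30, percentile 99.8). FSCN1, the actin-bundling protein of filopodia, had 3391 and 10550 reads (1.73), the actin-severing CFL1 0.95 and the tropomyosin TPM4 0.82. The integrin list lost its place by its mean (percentile 77.59) and the actin list when only genes with whole counts were kept (8 members, percentile 61.89).

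Among signalling lists, TGF-beta and SMAD targets were lower in library D1, with 14 of 17 members below 0, 2 at least 2-fold lower and 1 higher (median -0.45, percentile 0.01). The inhibitory SMAD6 had 31 and 10 reads (-1.49), the activin subunit gene INHBA 51 and 22 (-1.10), and the inhibitor of differentiation ID1 was higher (1.33). ERK feedback genes had 4 of 18 members at least 2-fold lower (median -0.22, percentile 1.16). These were the Sprouty genes SPRY1 (23 and 5 reads), SPRY2 (-1.30) and SPRY4 (-1.10), and EREG, a ligand of the EGF receptor (-1.47). The 10 ERK feedback members with whole counts did not stand apart (percentile 24.38).

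The other signalling lists did not stand apart in the main setting. YAP/TEAD targets had 3 of 17 members at least 2-fold lower, namely the growth factor TGFB2 (-2.22), DLC1 (-1.26) and NT5E (-1.21); their median of 0.04 and mean of -0.14 differed in sign (percentile 55.58, or 0.7 for the 11 members with whole counts). Among 9 Wnt targets, LEF1 was at least 2-fold higher (1.19, from 24 and 52 reads), with a median of 0.04 (percentile 61.06). The signs of the YAP/TEAD and Wnt medians changed under plain library totals. Immediate early genes had 1 of 21 members at least 2-fold higher, the AP-1 subunit FOSL1 (1.10), with a median of -0.11 (percentile 10.28, or 0.27 for the 16 members at 10 CPM or more). The PI3K, AKT and mTOR list had 1 of 22, the mTOR inhibitor gene DDIT4 (1.58), with a median of -0.08 and a mean of 0.08 (percentile 5.98).

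The list of amino acid and endoplasmic reticulum (ER) stress genes stood apart above, with members on both sides. Of 25 members, 6 were at least 2-fold higher and 1 lower, while 16 lay above 0 and 9 below (median 0.31, percentile 99.85). PSAT1 (1.98), the amino acid transporter SLC7A5 (1.51) and the secreted glycoprotein gene STC2 (1.53) were joined by ASNS, asparagine synthetase (1.41), CHAC1, a glutathione-degrading enzyme (1.41), and PHGDH, the first enzyme of serine synthesis (1.05). The ER chaperone gene DNAJB9 was the lower member (-1.44), and the chaperone genes HSPA5 and CALR had ratios of -0.35 and -0.50. ASNS, CHAC1, PHGDH, HSPA5 and CALR were named after their values were seen. The list's place depended on which members were kept, since its 10 members with whole counts had a median of -0.13 at percentile 1.91.

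Hypoxia and glycolysis genes were higher in library D1, with 20 of 23 members above 0 and 3 at least 2-fold higher (median 0.37, percentile 99.93). These were CA9, a carbonic anhydrase induced by hypoxia (1.29, from 15 and 35 reads), NDRG1, a hypoxia-responsive gene (1.24), and ADM, the vasodilator adrenomedullin (1.15). Cholesterol genes did not stand apart (median 0.03, a sign that changed under plain library totals, percentile 37.06), with the mevalonate kinase gene MVK at 0.56 and INSIG1, which restrains sterol synthesis, at -0.48. NRF2 targets gave 1 of 20 members at 2-fold, the aldo-keto reductase AKR1C2 (1.54, from 22 and 61 reads). Their median was 0.15 (percentile 86.9, or 99.21 by the mean and 48.88 for the 11 members with whole counts). Heat shock genes gave none of 17 (median 0.26, percentile 89.92, or 98.84 with unmatched random lists and 60.94 by the mean), with HSPB1 at 0.67 and DNAJB4 at -0.61.

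**Figure D3:**
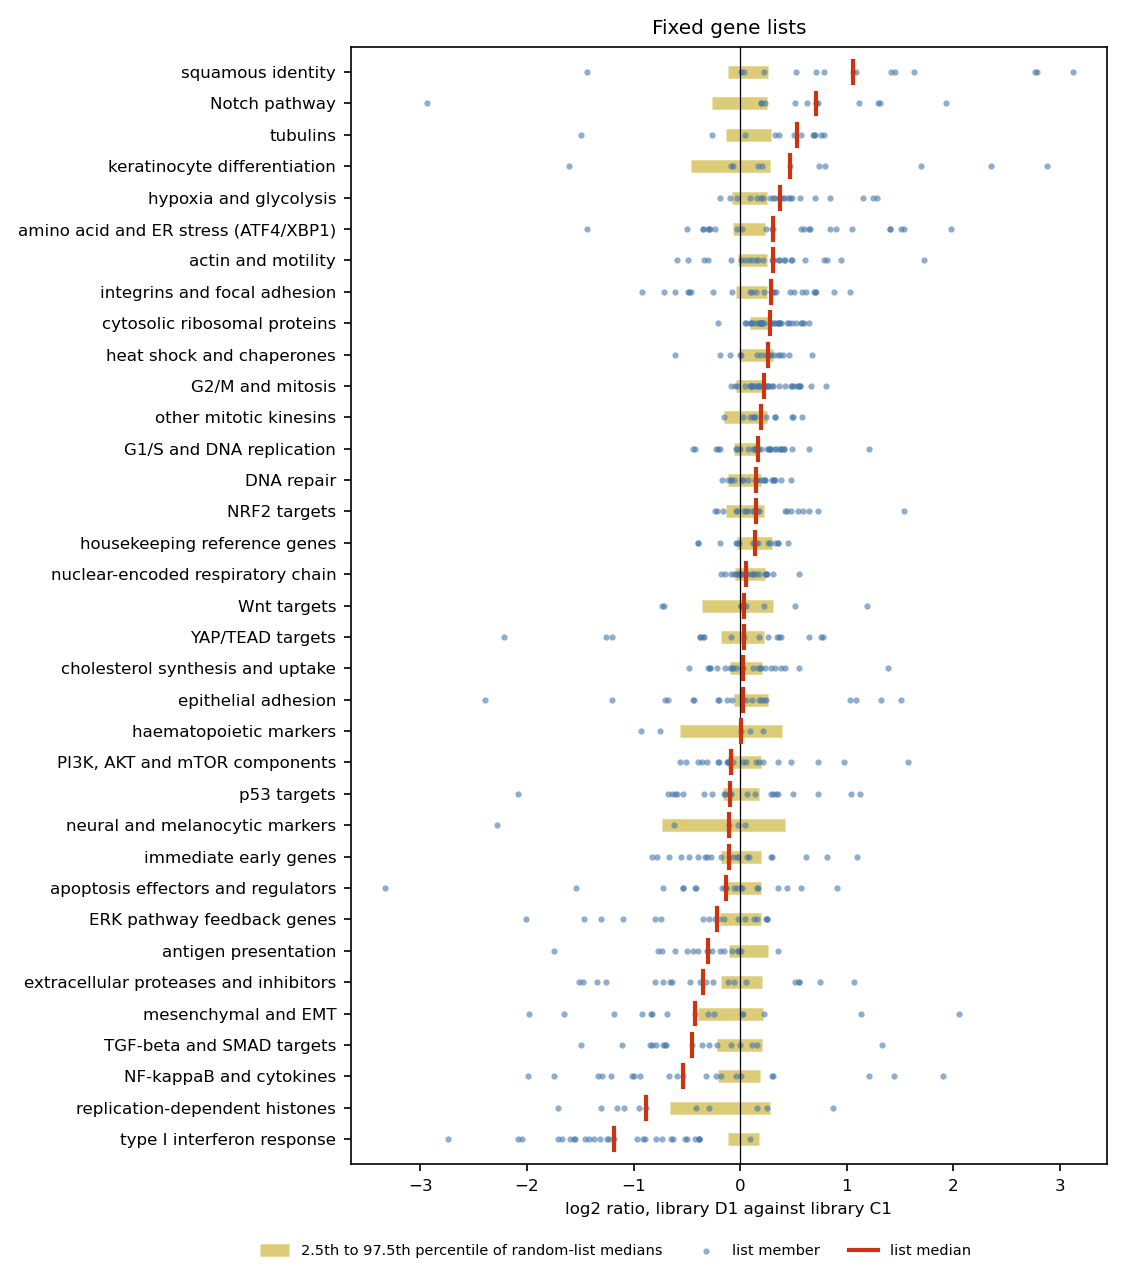
For each fixed list with at least 5 measured members, blue points are the log2 ratios of its members in library D1 against library C1 (x axis), the red line is the median, and the yellow bar spans the central 95% of random-list medians. Squamous identity has the highest median at 1.06 and the type I interferon response the lowest at -1.18; medians between 0 and 0.12 change sign under plain library totals.

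Housekeeping genes did not stand apart, with none of 16 at 2-fold (median 0.14, percentile 44.46). Nuclear-encoded respiratory chain genes behaved alike (none of 24, median 0.06 with a sign that changed under plain library totals, percentile 33.96). Cytosolic ribosomal protein genes had 32 of 33 members above 0 (median 0.28, percentile 96.47). The percentile was 97.58 to 99.99 under 5 of the alternatives, but 87.76 with matching in 50 bins and 92.69 by the mean of the list. The 84 genes of that family took 5.78% of the counts in library C1 and 6.68% in library D1. Mitochondrially encoded mRNAs and nuclear-retained or small structural RNAs were not analysed here.

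Markers of other kinds of cell that had a value were mostly low in both libraries. Haematopoietic markers had 5 members past the filter, none at 2-fold (median 0.01 and mean -0.27, the sign of the median changing under plain library totals, percentile 58.56), and the 9 with a value had a median of -0.34 without the filter (percentile 12.39). Neural and melanocytic markers had 5 (median -0.10, percentile 51.15), of which the microtubule-associated MAP2 had 95 and 18 reads (-2.28). Of 4 endothelial markers, the cadherin gene CDH5 had 1000 and 249 reads (-1.91) and ESAM 26 and 5 (-2.18), while the transcription factor gene ERG had 21 and 40, just past 2-fold higher, and VWF 22 and 29 (0.48). COL1A1 (-1.18) was the only fibroblast marker past the filter, and SERPINA1, an antiprotease, with 2088 and 996 reads (-0.98), the only hepatic or intestinal one.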

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

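The deposited TPM, the genes with whole counts, and the random lists matched on transcript length or GC content were chosen after the data were seen; the other alternatives were fixed before. No paired analysis was possible because each group had 1 library and no test was run. KIF2C stayed higher in library D1 under every alternative run on it, with its lowest log2 ratios at 1.93 under library totals and 1.90 from the deposited TPM. The genes at least 2-fold higher and lower in library D1 numbered 1040 and 1669 without the expression filter, 171 and 216 at 10 CPM or more, and 143 and 243 when the whole counting interval had to lie beyond 2-fold. They numbered 1053 and 1402 at 1.5-fold and 80 and 202 at 3-fold, differences that follow from the size asked for. Among the 5895 genes with whole counts they numbered 179 and 334 at 2-fold. This was a larger share than among all genes past the filter, for a reason not tested.

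Of 411 percentiles of lists recomputed under the alternatives, 385 kept the call, standing apart on the same side or not standing apart, although some of the latter moved far, as p53 targets did from 11.73 to 85.97 with whole counts only. The alternative scalings shift the ratios of a list and of its random lists alike. Their percentiles were therefore nearly fixed in advance, and the calls kept under them are no check. The proteases, squamous identity, type I interferon, antigen presentation, TGF-beta, Notch and hypoxia lists stood apart under every alternative run, 7 of the 17 that stood apart. The mesenchymal list was at percentile 4.31 with 5 counts added, 7.85 without the filter and 9.85 by its mean, and histones were at 47.1 and 13.9 under the last 2 of these. Integrins were at 77.59 by their mean. The G1/S list moved outward to 98.21 with unmatched random lists and 97.6 by its mean. With whole counts only, G2/M genes were at 95.05 (24 members) and actin genes at 61.89 (8 members). Under that setting the YAP/TEAD list turned to 0.7 (11 members) and the amino acid and ER stress list to 1.91 (10 members); the setting drops members of each list, and no other cause was tested. The 162 named genes other than KIF2C were recomputed under 4 alternatives only: DESeq2 size factors, library totals, upper-quartile scaling and 5 added counts. Of their 648 ratios, 583 stayed within their counting interval and 65 moved beyond it. Among genes whose interval excluded 0, 0 changed sign. Each scaling shifts every ratio by the same amount, -0.12 under library totals, so these results largely reflect the width of each interval. Sign changes of genes whose interval held 0 were not counted. Depth limits what can be said of genes near 1 CPM, which is about 19.0 reads in library C1 and 17.8 in library D1.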

Other observations

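The genes of the first 2 paragraphs and every test below were chosen after the results were seen. What the tests of transcript length and GC content would show, and the members of the secretory and further basal lists, were written down before the values of those tests were examined. Beside TXNIP, its relative ARRDC4, another glucose-responsive arrestin, had 462 reads in library C1 and 71 in library D1 (log2 ratio -2.60). The glycine transporter gene SLC6A9 had a log2 ratio of 2.14, the mitochondrial folate enzyme gene ALDH1L2 2.03, the mitochondrial PEP carboxykinase gene PCK2 1.44, and CBS, which makes cystathionine from serine, 1.29. The nuclear lamina gene LMNB1 had 1364 and 4229 reads (1.72), the chaperonin subunit gene CCT6A 1.45, and MAPRE1, which encodes the microtubule end-binding protein EB1, 1.19. The epithelial 14-3-3 gene SFN was higher in library D1 at 1.88, as were the neurotrophin receptor gene NGFR at 1.60 and the growth factor gene NRG1 at 1.58. On the lower side lay the secreted glycoprotein gene STC1 (-2.43), the membrane protein gene TM4SF1 (-1.63), the semaphorin and VEGF receptor gene NRP1 (-1.50) and the complement gene C3 (-1.47).

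Among genes with at least 30 reads in 1 library, 7 were listed at 0 in library D1 and 2, CDRT4 and ZNF177, at 0 in library C1. RNF103-CHMP3, a read-through symbol that shares exons with both of its parent genes, had 87 reads in library C1 and 0 in library D1, and TMEM140 had 40 and 0. Interferon genes themselves were near the limit of detection, with 13 and 3 reads of IFNL1 (-1.86, interval -4.48 to -0.16) and 1 and 0 reads of IFNB1.

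KIF2C was higher in library D1, against the reading of C as control and D as knock-down. Reads moved between relatives could not account for it, since KIF2A was lower by 377 reads and KIF2C higher by 2253. A difference in proliferation of the cells did not either, since the highest of 47 other G2/M and mitotic kinesin genes, ANLN, had a log2 ratio of 0.81, below the interval of KIF2C. Exchanged or misread codes may account for it: KIF2C ranked 3rd of 4170 genes of like abundance, which sets KIF2C apart from its peers but cannot tell this explanation from others, as KIF2C is itself the pattern. Whether KIF2C mRNA was instead higher in the knockdown library was not tested and stays open.

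Interferon response genes were lower in library D1. Scaling of the libraries did not explain this, since the list median lay between -1.3 and -1.18 under 4 scalings. Blood cells in library C1 stay open, since the share of them that the pattern would need is not known and 9 of the 14 haematopoietic markers had a value (median -0.34 with an SD of 0.58 across markers); LCP1 and CD68, abundant in both libraries, had ratios of 0.01 and 0.09, while PTPRC (-0.34), CD3E (-1.01) and CSF1R (-1.13) had 15 reads or fewer in each library. With random lists matched on transcript length or GC content, the list stayed at percentile 0.0. The KIF2C condition, a response to the shRNA or its delivery, and culture differences such as density each may lie behind it, and 1 library per condition leaves them open and untested.

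Reads moved between keratin genes did not explain the higher squamous identity genes of library D1, since the summed keratin reads had a log2 ratio of 2.02 and the other members a median of 0.52, nor did transcript length or GC content, with the list at percentile 100 under both matchings. Cells of the 4 non-epithelial kinds in library C1 did not explain it: they would lower all epithelial genes there alike, and the 21 epithelial adhesion genes had a median of 0.02 with an SD of 0.87 across genes, below the list median of 1.06 by more than that SD; nor did hepatic or intestinal cells, which would have to make up about 52.0% of library C1, since 5 of their 6 markers with a value, ALB among them at 0 reads in library C1 and 1 in library D1, lay below 1 CPM in both libraries, the other being SERPINA1 (2088 and 996 reads). A hypothesis, formed from this pattern and the low AGR2 and MUC5AC, is that library D1 was in a more basal and less secretory epithelial state: a secretory and simple epithelial list (18 members, 6 at least 2-fold lower and 0 higher, median -0.56) lay at percentile 0.02 and a further basal list (16 members, 2 at least 2-fold higher and 0 lower, median 0.53) at percentile 100, which is consistent with it. Members differed within both lists, with FOXA1 at -1.14 but the simple keratins KRT8, KRT18 and KRT19 at -0.06, 0.06 and 0.77, and with COL17A1 at 1.04 but TFAP2C at -0.53. The KIF2C condition, the shRNA vector and culture differences stay open as the origin of the pattern, untested with 1 library each.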
